A study of Mus musculus with 3 samples.

How the data were processed

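RNA from 3 samples labelled as replicates of mpkDCT4a cells was sequenced after removal of ribosomal RNA, from 500 ng of total RNA fragmented to about 300 bp, per the labels. The deposited table holds whole-number counts of reads per Ensembl gene and library, not normalised. Per the submitters' processing notes, reads were aligned to mm10 (GRCm38) with tools that include STAR and HTSeq. Their versions, settings, strand setting, annotation release and treatment of reads with several matches are not given in the sources used here. HTSeq as commonly run leaves out reads that match several places, which lowers the counts of genes with near-identical copies. Whether this was done here is not stated. Table columns were assigned to replicates by the number at the end of their names.

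Gene names, positions and exon lengths came from GENCODE M21, the same genome build. 55227 of 55487 gene identifiers matched, and the 260 others held 313 counts (0.0230%). No line of the table lacked a gene and no column went unused. Library sizes were the total counts scaled by the trimmed mean of M-values in edgeR 4.0.16 under R 4.3.3, with factors of 0.992, 1.00 and 1.01. Levels are in CPM of these sizes. A gene was called detected at a mean of at least 1 CPM. Python libraries were numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

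Each gene's 3 counts were tested against counts in proportion to library size by a chi-square test with Benjamini-Hochberg adjustment and a threshold of 0.05. The spread between libraries beyond counting error was estimated as edgeR's biological coefficient of variation with an intercept only. For each of 37 gene lists fixed before the data were examined, the median level was ranked among 10000 random lists of protein-coding genes of the same size, as a description and not a test, since genes are not replicates. Gene pairs were compared as log2 ratios of CPM + 0.5 per library with an exact sign-flip permutation test, and as ratios of summed counts with 95% exact binomial intervals. A ratio against a gene with 0 counts was computed against 3 counts over all libraries and is given as at least that value. It leaves out the counting error of the gene with counts, so it is not a 95% limit. The share of each gene's 50-base stretches, on either strand, that occur in an annotated transcript of another gene was counted to find genes that share reads. The read length is not given in the sources used here, and longer reads would share less.

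The genes named were set by a rule. It takes all members of the distal convoluted tubule and cotransporter lists and of the pairs, the 4 highest members of every other list with up to 4 of the members below 1 CPM, the 20 highest genes, up to 10 varying genes with a mean of at least 10 CPM, and the 15 highest transcription factors. Hoxb13, the remaining mitochondrial messages, Slc8a1, Scnn1g, Pou3f3, Foxi1, Gata2, Six2 and Wt1 fall outside the rule and were named after their values were seen, as were the gene families of the closing observations. Some genes and pairs that the rule takes are not reported here.

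Counts per library were 436983, 482418 and 443192, and 7404, 7625 and 7468 genes had at least 10 counts. Protein-coding genes took 96.2%, 96.8% and 96.9% of counts, ribosomal RNA genes 1.69%, 1.19% and 1.04%, and the 10 highest genes 5.68%, 5.12% and 4.96%. On simulated counts for the 12473 genes with 200 of them changed in 1 library, the chi-square test recovered 9.5% of genes changed 1.5-fold, 31.5% changed 2-fold and 72.5% changed 4-fold, with 0, 3 and 10 false calls. Among genes of at least 20 CPM it recovered 12.0%, 63.0% and 100% with 1, 5 and 7 false calls, and it made 0 calls with no gene changed. These counts were simulated with counting error alone, so the false calls do not carry over to libraries with further spread. Simulated coefficients of variation of 0.1, 0.2 and 0.4 were recovered as 0.0981, 0.198 and 0.397, and one of 0 as 0.00988.

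Alternatives were DESeq2 1.42.0 size factors or library totals in place of the trimmed mean, other thresholds and filters, TPM from exon lengths, other pseudocounts, random lists drawn from genes with a count, and leaving out each replicate. An exact multinomial test for genes with up to 300 counts was added after the data were seen. Comparisons between conditions were not made, since the labels give 1 group.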

Results

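Gene expression was measured in mpkDCT4a cells, an immortalised cell line from the distal convoluted tubule of the mouse kidney, the nephron segment that takes up sodium chloride through a thiazide-sensitive cotransporter. The series title places these libraries in a study of how gene regulation is arranged in three-dimensional space in this segment. 3 libraries of total RNA depleted of ribosomal RNA made up 1 group of unmodified cells, so no comparison between conditions could be made. Cells had been kept at 37 °C in a medium that held insulin (5 µg/ml), glucose (20 mM), the glucocorticoid dexamethasone (50 nM), the thyroid hormone triiodothyronine (1 nM), epidermal growth factor (10 ng/ml) and serum (2%). The questions that this design can answer are which genes the line expressed, at what level, and how far the replicates differed.

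The libraries held 436983, 482418 and 443192 counts in replicates 1, 2 and 3, and 1 count was worth 2.31, 2.07 and 2.24 counts-per-million (CPM) in them. The labels do not say whether these totals come from shallow sequencing or from a part of the reads, and a gene with 0 counts here may have counts at a greater depth. 12473 of 55487 genes reached a mean of 1 CPM, which at this depth takes 2 counts over the 3 libraries and is called detected from here on. Of these, 3364 lay between 1 and 10 CPM, 6416 between 10 and 100 CPM and 2693 at 100 CPM or more. The detected genes included 11122 of 21974 protein-coding genes, whose median was 39.6 CPM. A gene with 0 counts in all 3 libraries may have had up to 2.20 CPM (3 counts of the summed total), or 6.92, 6.21 and 6.72 CPM in the single libraries. Levels are given as mean ± SD over the 3 libraries, and intervals and limits cover counting error only. They were not divided by gene length unless transcripts-per-million (TPM) are named, so a level ranks genes by reads rather than by molecules. For a list, the median is taken over the means of its genes. The SD beside it is that of the medians within the single libraries.

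The genes that differed between the replicates were non-coding RNAs, most of them ribosomal, and 1 protein-coding gene. The nuclear ribosomal RNA gene CT010467.1 (ENSMUSG00000106106, GRCm38 chromosome 17, 39846353 to 39848827, minus strand) had 7361, 5736 and 4625 counts in replicates 1, 2 and 3. The mitochondrial ribosomal RNAs mt-Rnr1 (136, 96 and 67 counts) and mt-Rnr2 (207, 128 and 169 counts) also differed, as did Rn7sk, the RNA of the 7SK particle that holds back transcription elongation (2418, 2244 and 2328 counts). The only protein-coding gene among them was Lars2, the mitochondrial leucyl-tRNA synthetase, at 421, 359 and 311 counts. These 5 of 12473 genes passed a chi-square test of each gene's counts against counting error with Benjamini-Hochberg adjustment, with adjusted p-values of 1.47e-173 for CT010467.1, 1.55e-05 for Rn7sk, 0.00255 for each mitochondrial ribosomal RNA and 0.0171 for Lars2. The count of genes at an unadjusted p under 0.05 was 610, or 4.89%. With replicate 1 left out only CT010467.1 passed. Without replicate 2, CT010467.1, Lars2 and mt-Rnr1 passed, and without replicate 3, CT010467.1, Rn7sk and mt-Rnr2. Of the 50-base stretches of CT010467.1 and Rn7sk, 69.1% and 68.1% also occur in transcripts of other annotated genes, so their counts are uncertain.

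For most genes the replicates lay close to counting error. Over 8983 genes with a mean of at least 5 counts, the chi-square statistic per gene was 1.09 between replicates 1 and 2, 1.12 between 1 and 3 and 1.05 between 2 and 3, where counting error alone gives about 1.00. All pairs differed by more than counting error (chi-square p = 1.36e-08, 8.62e-16 and 0.000713), also with CT010467.1 set aside (chi-square p = 0.00494, 0.00155 and 0.00219), so no library was taken for a second copy of another. The biological coefficient of variation estimated with edgeR was 0.0394. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

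Markers of the distal convoluted tubule were partly expressed. Of 12 markers 5 were detected, and the highest was Wnk4, a kinase of the pathway that regulates the sodium chloride cotransporter, at 45.2 ± 11.2 CPM (ENSMUSG00000035112, chromosome 11, 101260567 to 101277409, plus strand; 24, 16 and 21 counts). Cnnm2, a basolateral protein of magnesium transport, followed at 19.8 ± 3.23 CPM, then the magnesium channel Trpm6 at 8.84 ± 5.98 CPM and the potassium channel Kcnj10 at 6.67 ± 2.42 CPM. Egf had 3 counts in all and 2.23 ± 2.31 CPM. The cotransporter itself, Slc12a3 (ENSMUSG00000031766, chromosome 8, 94329201 to 94366214, plus strand), had 0 counts in every library, as did Pvalb, which encodes parvalbumin, the calcium-binding protein Calb1, the ubiquitin ligase adaptor Klhl3, the transcription factors Emx1 and Sall3, and Tmem52b. For each of these 7 genes, 0 counts leave a level of up to 2.20 CPM open. The median of the 12 markers was 0 CPM, percentile 14.1 of 10000 random lists of 12 protein-coding genes. For a median of 0 that percentile depends only on the length of the list. Many protein-coding genes had no count, so the percentile among lists drawn only from genes with a count is given as well, as the counted-gene percentile, and it was 0 for every list with a median of 0. Each list kept its own members without counts there, which lowers this percentile for lists that have such members. It is therefore not a rank of the list among expressed genes.

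**Figure D1:**
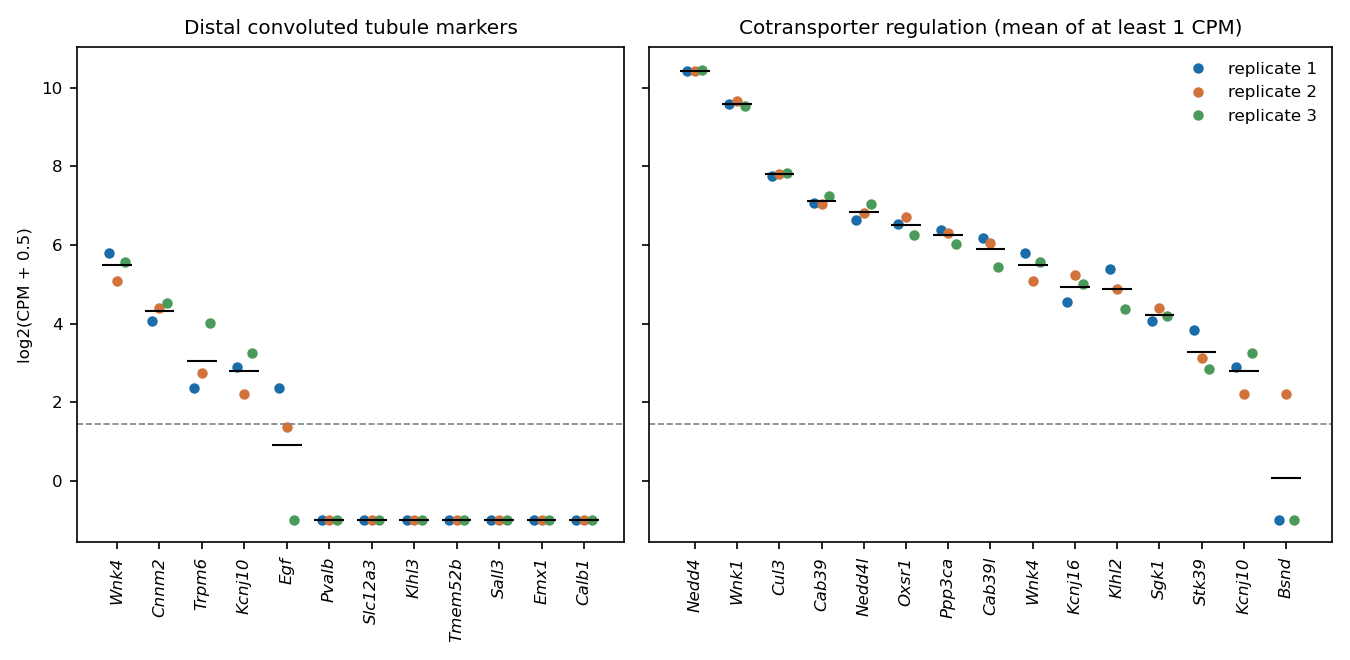
Levels of the distal convoluted tubule markers (left) and of the genes of cotransporter regulation with a mean of at least 1 CPM (right) as log2(CPM + 0.5), with 1 point per library and a bar at the mean of the 3 points; the dashed line is the limit of 2.20 CPM that 0 counts over the 3 libraries allow. Nedd4, at 1389 CPM, and Wnk1, at 775 CPM, lie highest, and Slc12a3, in the left panel, lies at 0 counts in all 3 libraries.

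The kinases and ubiquitin ligase parts that regulate the cotransporter were mostly present. Of 22 genes 15 were detected, with a median of 24.2 ± 3.20 CPM. Wnk1 stood at 775 ± 38.4 CPM (chromosome 6, 119923969 to 120038672, minus strand), and the downstream kinases differed, with Oxsr1 at 90.7 ± 13.8 CPM and Stk39, which encodes SPAK, at 9.62 ± 3.74 CPM. The ubiquitin ligases Nedd4 (1389 ± 22.7 CPM) and Nedd4l (114 ± 16.6 CPM) and the scaffold Cul3 (222 ± 4.68 CPM) were expressed, and Klhl2, the paralog of Klhl3, was at 30.2 ± 10.7 CPM. The kinase cofactors Cab39 and Cab39l were at 139 ± 11.8 and 60.1 ± 15.4 CPM, the calcineurin subunit Ppp3ca at 75.6 ± 9.44 CPM, the potassium channel Kcnj16 at 30.6 ± 7.13 CPM and the aldosterone-responsive kinase Sgk1 at 18.3 ± 2.30 CPM. The chloride channel subunit Bsnd had 2 counts and Wnk3 had 1, while Wnk2 and the phosphatase inhibitor Ppp1r1a had 0. The list's median lay at percentile 96.2, but the counted-gene percentile was 17.2.

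Pairs of related genes were compared within each library. Wnk1 had 17.3 times the counts of Wnk4 (95% counting interval 13.4 to 22.8) and Stk39 0.105 times those of Oxsr1 (0.0543 to 0.186), while per transcript length the ratio of Wnk1 to Wnk4 was 3.12. Slc12a2, the cotransporter of sodium, potassium and chloride that many cell types carry, had 382 counts and was at least 127-fold higher than Slc12a3. Slc12a1, its thick ascending limb relative, had 0 counts, so that no ratio of Slc12a3 to Slc12a1 could be given. Klhl2 was at least 13.7-fold higher than Klhl3. Sgk1 had 0.160 times the counts of Nedd4l (0.101 to 0.246), or 0.575 times its TPM. Of the 20 pairs fixed before the data were examined, 19 could be compared and 18 had the same direction in all 3 libraries. With 3 libraries the exact sign-flip test cannot give a p below 0.25, the value that all 18 reached.

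Most genes of magnesium handling were detected, and 7 of 12 of calcium handling. Of the 24 magnesium genes 21 were detected, with a median of 24.8 ± 3.93 CPM (percentile 96.8, counted-gene 16.5). Among the highest were the epidermal growth factor receptor gene Egfr (273 ± 48.5 CPM), the phosphatase Ptp4a2 (254 ± 23.3 CPM) and Magt1 (200.2 ± 17.0 CPM), and 3, namely Cnnm1, Fxyd2 and Kcna1, had no count. Trpm7, the broadly expressed relative of Trpm6, was at 177 ± 11.8 CPM, and Trpm6 had 0.0498 times its counts (0.0254 to 0.0886). Cnnm2 had 0.614 times the counts of Cnnm4, with an interval of 0.365 to 1.01 that includes no difference. The means of the calcium genes had a median of 1.42 CPM (percentile 42.9, counted-gene 0), but the median within each single library was 0 CPM. These genes included the plasma membrane calcium pump Atp2b1 at 251.5 ± 17.9 CPM, the receptor Fgfr1 at 46.7 ± 8.51 CPM, Atp2b4 at 5.05 ± 3.04 CPM and the parathyroid hormone receptor Pth1r at 1.52 ± 1.31 CPM. The calcium channels Trpv5 and Trpv6, both calbindins, Calb1 and S100g, and the exchanger Slc8a1 had 0 counts.

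Receptor genes for the hormones in the medium had counts, apart from Thrb. Of 23 receptor genes and partners 15 were detected, with a median of 5.32 ± 4.77 CPM (percentile 70.3, counted-gene 0.02). Igf1r was at 300.4 ± 12.4 CPM, Igf2r at 288 ± 33.9 CPM and the glucocorticoid receptor gene Nr3c1 at 148 ± 7.10 CPM. The mineralocorticoid receptor gene Nr3c2 had 1 count against 202 for Nr3c1, a ratio of 202 with a counting interval of 35.8 to 8018. Hsd11b2, which inactivates glucocorticoids, had 7 counts (4, 0 and 3) and Hsd11b1 had 0 (exact sign-flip p = 0.5). The thyroid hormone receptor gene Thra was at 19.9 ± 7.21 CPM and at least 9.0-fold higher than Thrb, which had 0 counts, and Egfr had 123 times the counts of its ligand Egf (41.9 to 601). Avpr2 was also among the 8 genes below 1 CPM, but 72.9% of its 50-base stretches occur in another gene, so its 0 counts are uncertain. Of 12 genes that respond to glucocorticoids 10 were detected, with a median of 27.7 ± 4.02 CPM (percentile 93.1, counted-gene 30.4), led by Fkbp5 (230 ± 23.8 CPM), Errfi1 (111 ± 18.8 CPM), the transcription factor Klf9 (80.8 ± 4.25 CPM) and the clock gene Per1 (56.9 ± 8.22 CPM). Cebpd had 1 count and Map3k6 had 0.

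Markers of the neighbouring nephron segments were mostly without counts. Of 12 markers of the late distal convoluted and connecting tubule, 2 were detected, the sodium channel subunit Scnn1a (11.4 ± 8.02 CPM; 3, 10 and 3 counts) and Hsd11b2 (5.32 ± 4.77 CPM). Scnn1a was at least 5.33-fold higher than its partner subunit Scnn1b, which had 0 counts, and Scnn1g had 1 count. Of 11 principal cell markers 2 were detected, Gata3 at 75.0 ± 16.6 CPM and Hsd11b2, and the water channel Aqp2 had 0 counts. None of 11 intercalated cell markers, including the proton pump subunits Atp6v1g3, Atp6v0d2 and Atp6v1b1 and the anion exchanger Slc4a1, had a count. Of 12 thick ascending limb markers 2 were detected, Cldn19 (4.28 ± 3.47 CPM) and Egf, and uromodulin (Umod) had 0 counts. Of 4 macula densa markers Ptgs2 was detected (5.15 ± 4.71 CPM). The medians of these 5 lists were 0 CPM, at percentiles of 14.1, 20.1, 20.1, 14.1 and 12.7.

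Some markers of other cell types were detected, in shares close to that of the distal convoluted tubule list for podocytes (3 of 8) and fibroblasts (4 of 10). At 10 CPM or more the podocyte list had 3 of 8 genes and the distal convoluted tubule list 2 of 12. Of 20 proximal tubule markers 5 were detected, led by the endocytic receptor gene Lrp2 (215 ± 14.1 CPM), the water channel Aqp1 (60.3 ± 17.8 CPM), Slc6a19 (8.91 ± 6.02 CPM) and Cubn (5.10 ± 0.964 CPM), whereas the phosphate transporter Slc34a1, the glucose transporter Slc5a2, the lactate transporter Slc5a12 and the organic anion transporter Slc22a6 had 0 counts. Of 8 podocyte markers 3 were detected, Podxl (116.5 ± 18.6 CPM), Synpo (30.2 ± 2.87 CPM) and Cdkn1c (14.6 ± 3.77 CPM), and the slit diaphragm gene Nphs1 had 0 counts. Of 9 endothelial markers only Flt1 was detected (10.3 ± 0.989 CPM). Of 10 leukocyte markers 2 were, the growth factor receptor gene Csf1r (45.8 ± 11.6 CPM) and Cd68 (3.72 ± 1.43 CPM), while Ptprc, Lyz2, Adgre1 and Cd3e had 0 counts. Fibroblast and smooth muscle markers had 4 of 10 detected, Tagln (7.31 ± 0.850 CPM), Col1a1 (7.25 ± 2.95 CPM), Acta2 (2.23 ± 2.31 CPM) and Pdgfrb (2.15 ± 2.08 CPM), and 5 erythroid markers had no count. Of the 50-base stretches of the globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, 72.3%, 89.3%, 53.2% and 58.3% occur in another annotated gene, and of those of Tagln 58.3%, so these counts are uncertain. The median of the fibroblast list was 0.718 ± 0.598 CPM (percentile 35.9, counted-gene 0). The medians of the proximal tubule, podocyte, endothelial, leukocyte and erythroid lists were 0 CPM (percentiles 14.2, 13.8, 20.5, 13.9 and 21.2).

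**Figure D2:**
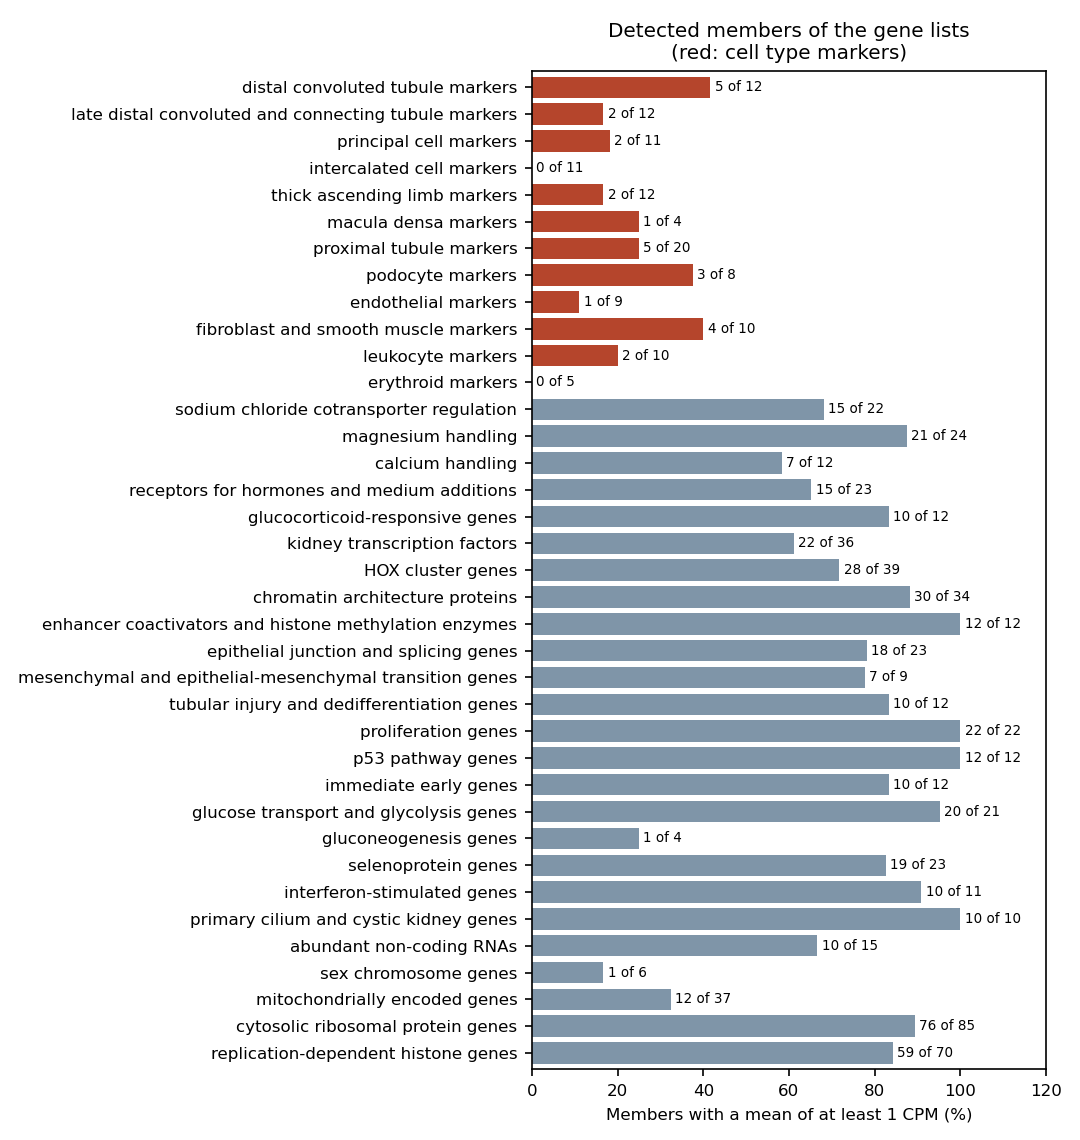
Percent of each gene list's members with a mean of at least 1 CPM over the 3 libraries, with the number of members beside each bar; red bars are cell type markers and grey bars the other lists. The distal convoluted tubule markers, at 5 of 12, lie close to the fibroblast and smooth muscle markers, at 4 of 10, and the podocyte markers, at 3 of 8, while all 22 proliferation genes and all 12 coactivator genes are detected.

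Of 36 kidney transcription factors 22 were detected, with a median of 7.65 ± 1.45 CPM (percentile 80.9, counted-gene 0). The highest was Tfcp2l1, a factor of the distal nephron and collecting duct, at 379 ± 16.1 CPM, followed by the nephric lineage factor Pax8 at 164 ± 22.0 CPM, Tfap2a at 139.5 ± 14.8 CPM, Sall1 at 134 ± 27.4 CPM, Esrrb at 113 ± 9.74 CPM and Mecom at 105 ± 9.41 CPM. Pax2 was at 82.4 ± 6.89 CPM, Gata3 at 75.0 ± 16.6 CPM, Sox9 at 71.9 ± 22.4 CPM, Sim1 at 57.1 ± 15.4 CPM and Irx2 at 54.8 ± 5.89 CPM. Elf3 (40.5 ± 2.80 CPM), Emx2 (37.9 ± 15.7 CPM) and Ppargc1a (29.4 ± 0.545 CPM) were also among the 15 highest. The 14 factors below 1 CPM included Hnf4a and Hnf4g, which act in the proximal tubule, and Emx1, each with 0 counts, and also factors of the distal nephron and of kidney development such as Sall3, Pou3f3, Foxi1, Gata2, Six2 and Wt1, which had 0 counts too. Pax2 had 0.505 times the counts of Pax8 (0.398 to 0.636).

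HOX genes, which mark position along the body axis, were expressed from all 4 clusters. Of 39 genes 28 were detected, with a median of 5.16 ± 1.26 CPM (percentile 74.3, counted-gene 0), led by Hoxb9 (157 ± 15.9 CPM), Hoxd8 (116 ± 29.5 CPM), Hoxd9 (49.7 ± 14.2 CPM) and Hoxc10 (40.9 ± 12.3 CPM). When split by paralog group, a grouping chosen after the values were seen, 11 of the 12 genes of groups 7 to 10 reached 10 CPM, with a median of 35.2 CPM. Of the 18 genes of groups 1 to 6, 15 were detected but 3 reached 10 CPM (median 3.36 CPM), and of the 9 genes of groups 11 to 13, 2 were detected, with Hoxb13 at 15.5 ± 2.65 CPM.

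**Figure D3:**
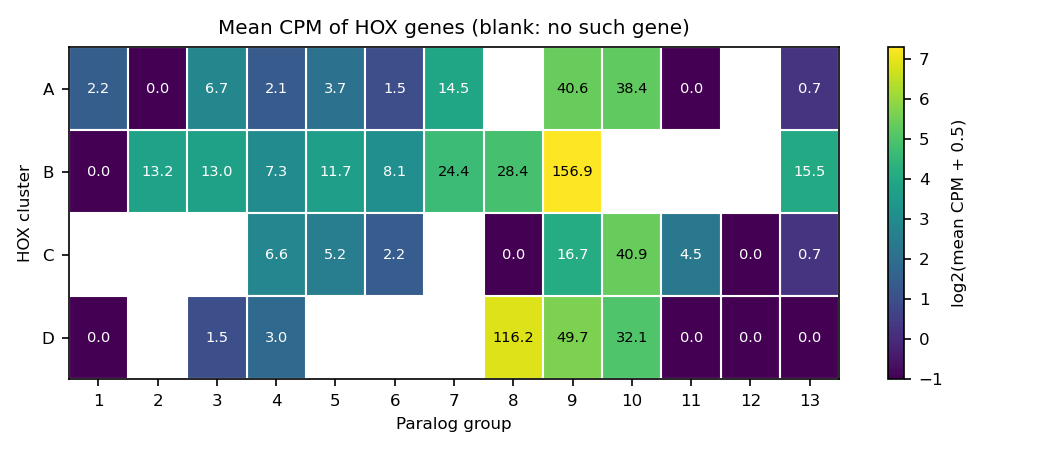
Mean level of each HOX gene over the 3 libraries, by cluster (rows) and paralog group (columns), with the CPM printed in the cell and the colour giving log2(mean CPM + 0.5). The highest cells are Hoxb9 at 157 CPM and Hoxd8 at 116 CPM, and groups 7 to 10 hold most of the genes at 10 CPM or more.

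Transcripts of chromatin architecture genes, a list that spans cohesin, condensin, insulator and topoisomerase genes, were at high levels. Of 34 chromatin architecture genes 30 were detected, with a median of 175 ± 7.56 CPM, above all 10000 random lists. Top2a, the replication-linked topoisomerase, was at 1160 ± 34.8 CPM, the cohesin subunit Rad21 at 625 ± 55.7 CPM, the condensin subunit Smc4 at 449 ± 21.8 CPM and the cohesin regulator Pds5a at 434 ± 22.4 CPM. Ctcf, the insulator protein that bounds loops, was at 165 ± 1.37 CPM and at least 75.0-fold higher than its germline paralog Ctcfl. The genes without counts were Ctcfl and the meiotic cohesin subunits Rad21l, Smc1b and Stag3. Stag2 had 1.23 times the counts of Stag1 (1.05 to 1.44), or 1.74 times its TPM. All 12 enhancer coactivator and histone methylation genes were detected, with a median of 207 ± 11.1 CPM, again above all random lists, with Crebbp (398 ± 26.8 CPM), Med1 (385 ± 11.9 CPM) and the Polycomb subunit Suz12 (317 ± 6.93 CPM) among the highest.

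Epithelial and mesenchymal genes were expressed together. Of 23 epithelial genes 18 were detected, with a median of 22.0 ± 3.79 CPM (percentile 94.8, counted-gene 12.3), led by the keratins Krt18 (420 ± 15.5 CPM) and Krt7 (409 ± 38.1 CPM), the tight junction gene Tjp1 (392 ± 43.7 CPM) and the desmosome gene Dsp (380 ± 9.28 CPM). Those without a count included the splicing regulator Esrp1 and the claudins Cldn7 and Cldn8. Of 9 mesenchymal genes 7 were detected, with a median of 16.7 ± 3.55 CPM (percentile 80.0, counted-gene 13.7), led by vimentin (Vim, 1552 ± 98.4 CPM), fibronectin (Fn1, 1435 ± 54.8 CPM), N-cadherin (Cdh2, 262.5 ± 25.7 CPM) and Zeb1 (108 ± 8.47 CPM), with Snai1 and Snai2 below 1 CPM. E-cadherin (Cdh1) had 0.246 times the counts of Cdh2 (0.192 to 0.311) and Krt8 0.177 times those of Vim (0.158 to 0.198). In TPM these ratios were 0.430 and 0.429. Krt8 shares 29.7% of its 50-base stretches with other genes and Vim 0%, so the ratio of Krt8 to Vim is uncertain. Of 12 genes of tubular injury 10 were detected, with a median of 71.0 ± 12.5 CPM (percentile 99.8, counted-gene 92.2). They were led by Vim, Cd24a (748 ± 7.22 CPM), the osteopontin gene Spp1 (289.5 ± 32.4 CPM) and Cd44 (147 ± 14.6 CPM), whereas the injury marker Havcr1 had 0 counts.

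Proliferation genes were expressed throughout. All 22 proliferation genes were detected, with a median of 240.1 ± 26.9 CPM, above all random lists, led by Top2a, Mki67 (643 ± 62.8 CPM) and the replication helicase subunits Mcm7 (449 ± 23.8 CPM) and Mcm4 (376 ± 41.5 CPM). All 12 genes of the p53 pathway were detected, with a median of 53.3 ± 6.25 CPM (percentile 99.3, counted-gene 78.7), including Ccng1 (314 ± 15.8 CPM), Trp53 (233 ± 31.2 CPM), Mdm2 (140.5 ± 23.1 CPM) and Zmat3 (139.6 ± 26.7 CPM). Histone genes of the replicating cell had 59 of 70 members detected and a median of 112 ± 2.20 CPM, led by Hist1h4d (871 ± 54.3 CPM), Hist1h1d (854 ± 52.7 CPM), Hist1h1e (838 ± 15.6 CPM) and Hist1h1c (778 ± 61.1 CPM). Of 12 immediate early genes 10 were detected, with a median of 19.4 ± 3.01 CPM (percentile 87.1, counted-gene 13.1), led by Jund (264 ± 26.4 CPM), Egr1 (70.4 ± 7.14 CPM), Myc (63.7 ± 16.2 CPM) and Jun (42.4 ± 6.02 CPM), while Fos had 1 count. Jund shares 48.3% of its 50-base stretches with other genes, and many histone genes share more, so these levels are uncertain.

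Of 21 glycolysis and glucose transport genes 20 were detected, with a median of 124 ± 2.12 CPM, led by Pkm (1303 ± 46.2 CPM), Gapdh (823 ± 48.8 CPM), Aldoa (721 ± 53.1 CPM) and Ldha (527 ± 52.2 CPM). Of 4 genes listed for gluconeogenesis the pyruvate carboxylase gene Pcx was detected (16.2 ± 2.03 CPM), Pck1 had 1 count, and G6pc and Fbp1 had 0, for a median of 0.373 ± 0.647 CPM (percentile 27.4, or 13.7 without replicate 3, counted-gene 0). The counted-gene value is 0 by construction, since any gene with a count has a mean of at least 0.690 CPM. Of 23 genes of selenoproteins and their synthesis, relevant because the medium held selenate, 19 were detected, with a median of 37.2 ± 2.88 CPM (percentile 99.2, counted-gene 55.2), led by Txnrd1 (616 ± 33.0 CPM), Selenot (272 ± 17.1 CPM), Gpx1 (193 ± 24.0 CPM) and Selenoi (184 ± 14.1 CPM). The others, Gpx2 and the deiodinases Dio1, Dio2 and Dio3, had 0 counts. Ribosomal protein genes had 76 of 85 members detected and a median of 150 ± 8.25 CPM, led by Rpl4 (1029 ± 78.0 CPM), Rps2 (848 ± 48.5 CPM), Rpl8 (821 ± 53.4 CPM) and Rpl7 (613 ± 45.2 CPM). Rps2 is uncertain, as 43.0% of its 50-base stretches occur in other genes.

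Interferon-stimulated genes were low. Of 11 genes 10 were detected, with a median of 3.72 ± 0.244 CPM (percentile 60.7, counted-gene 0.285), led by Bst2 (25.9 ± 5.90 CPM), Ddx58 (17.6 ± 4.37 CPM) and Ifit3 (13.1 ± 6.0 CPM), and Mx1 had 0 counts. Ifit3 shares 51.2% of its 50-base stretches with other genes, and its level is uncertain. All 10 genes of the primary cilium and of cystic kidney disease were detected, with a median of 43.0 ± 5.76 CPM (percentile 96.6, counted-gene 61.8), led by Pkhd1 (218 ± 38.7 CPM), Pkd2 (154.5 ± 10.5 CPM), Pkd1 (119 ± 7.87 CPM) and Kif3a (55.9 ± 10.1 CPM). Among the sex chromosome genes Xist, the RNA of X inactivation, was at 768 ± 33.4 CPM, and its antisense partner Tsix and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in every library. Of 15 non-coding RNAs 10 were detected, with a median of 5.26 ± 2.84 CPM, led by Rn7sk (5147 ± 470 CPM), Malat1 (4102 ± 90.1 CPM), Neat1 (134 ± 25.8 CPM) and Snhg1 (96.2 ± 19.1 CPM).

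Ranked by counts, the 20 highest genes included 2 for elongation factors of translation and several for the cytoskeleton. After CT010467.1 (13074 ± 3470 CPM) came Actb (7512 ± 281 CPM), Rn7sk, the scaffold Ahnak (4884 ± 77.3 CPM), the elongation factor Eef2 (4293 ± 99.8 CPM), Malat1, Eef1a1 (3703 ± 149 CPM), the chaperone Hsp90ab1 (3499 ± 227.5 CPM) and the fatty acid desaturase Scd2 (3172 ± 131 CPM). Non-muscle myosin Myh9 (3164 ± 120 CPM), filamin (Flna, 2582 ± 126 CPM), mt-Co1 (2487 ± 102 CPM), Akap12 (2326 ± 17.8 CPM), spectrin (Sptan1, 2136 ± 129 CPM) and the ATP synthase subunit Atp5b (1851 ± 25.6 CPM) followed. The list of 20 ended with Tubb5 (1830 ± 36.6 CPM), clathrin (Cltc, 1740 ± 25.8 CPM), Ddb1 (1613 ± 20.1 CPM), calnexin (Canx, 1577 ± 4.91 CPM) and Vim. Of the 50-base stretches of Eef1a1, 40.4% also occur in other annotated genes, so its level is uncertain.

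Of the mitochondrial genes, some messages were abundant and others had no count. Of 37 mitochondrially encoded genes 12 were detected (median 0 CPM), led by the messages mt-Co1, mt-Nd1 (1502 ± 46.7 CPM), mt-Cytb (869 ± 59.0 CPM) and mt-Nd5 (395 ± 13 CPM). Of the 13 messages, 7 had counts, with mt-Nd2 at 379 ± 45.6 CPM, mt-Nd4 at 335 ± 16.8 CPM and mt-Nd6 at 188 ± 26.2 CPM. The other 6, mt-Co2, mt-Atp8, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l, had 0 counts in every library and lie side by side at positions 7013 to 10173 of the mitochondrial chromosome. At least 98.0% of the 50-base stretches of these genes other than mt-Atp8 also occur in annotated nuclear pseudogenes, so their counts are uncertain. The levels of mt-Co1 and mt-Nd4 are uncertain for the same reason, with 51.1% and 62.2% shared.

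**Figure D4:**
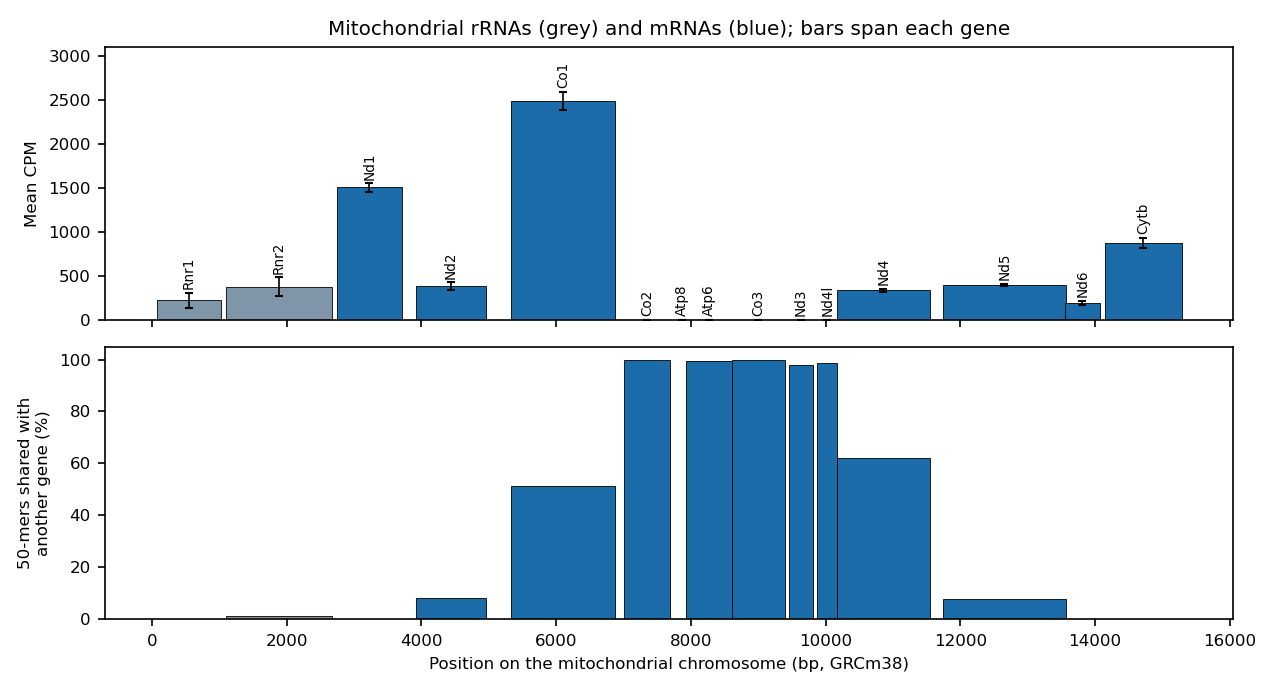
Mitochondrial messages (blue) and ribosomal RNAs (grey) along the mitochondrial chromosome; the upper panel gives the mean CPM with the SD over the 3 libraries, and the lower panel the percent of 50-base stretches that occur in transcripts of another annotated gene. The 6 messages without counts lie between positions 7013 and 10173.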

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

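The exact multinomial test was chosen after the data were seen, and all other alternatives before. The threshold moved the number of detected genes: 12473 genes were detected at 1 CPM, 14608 at 0.5 CPM, 10256 at 5 CPM and 13771 at 1 TPM, but 6775 had 10 counts in every library. The 5 varying genes were the same under DESeq2 size factors, library totals, no filter, a filter at 10 CPM and the exact test. Leaving out 1 replicate gave 1 to 3 genes, 1 of them without replicate 1, and fewer samples were then tested. The coefficient of variation was 0.0394 with and without the filter, since edgeR uses only genes with at least 5 counts, and 0.0321 to 0.0434 with 1 replicate left out, the lowest without replicate 1. The cause was not tested. The 18 pairs with 1 direction stayed 18 under TPM and other pseudocounts and were 18 to 19 with a replicate left out. The cotransporter list's percentile of 96.2 became 89.0 in TPM, and 17.2 against random lists from genes with a count, where all 12 cell type lists fell to 0, for medians of 0 by construction. With 1 replicate left out more random lists have a median of 0. The percentiles then became 15.7 to 15.9 for the distal convoluted tubule, connecting tubule and thick ascending limb lists, 21.9 to 22.0 for principal and intercalated cells, 13.5 to 13.7 for the macula densa, 16.3 for the proximal tubule, 15.3 for podocytes, 22.1 to 22.2 for endothelium, 15.4 to 15.7 for leukocytes and 22.5 to 22.6 for erythroid cells. Of all list percentiles under all alternatives 133 moved by no more than the SD between replicates or 0.5 points, whichever was larger, and 89 by more. Drawn against genes with a count, the magnesium, epithelial and transcription factor lists also fell, from 96.8, 94.8 and 80.9 to 16.5, 12.3 and 0. These lists and the cotransporter list kept their members without counts, which by itself lowers such percentiles. No gene pair changed direction. At this depth 0 counts leave up to 2.20 CPM open. No paired analysis was possible because there was 1 group.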

Other observations

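The gene families in this paragraph and the next were chosen after the data were seen. Among 365 solute carriers 181 were detected, led by the amino acid transporters Slc38a2 (886 ± 67.6 CPM) and Slc7a1 (634 ± 27.0 CPM), the mitochondrial phosphate carrier Slc25a3 (599.95 ± 66.8 CPM) and the osmolyte carriers Slc5a3 (463 ± 20.4 CPM), for inositol, and Slc6a6 (439 ± 30.7 CPM), for taurine. In the cation chloride cotransporter family 6 of 9 genes were detected, with Slc12a2 at 280.2 ± 23.2 CPM and the potassium chloride cotransporters Slc12a7 and Slc12a4 at 168.5 ± 17.9 and 141 ± 15.7 CPM. Potassium channels had 11 of 94 genes detected, led by Kcnk5 (93.2 ± 18.4 CPM) and Kcnk1 (83.0 ± 5.80 CPM), and transient receptor potential channels 6 of 24, led by the osmosensitive channel Trpv4 (195 ± 28.4 CPM). Chloride channels and anoctamins had 11 of 20 detected, with Ano6 at 367 ± 26.1 CPM, the endosomal exchanger Clcn5 at 264 ± 51.2 CPM and Cftr at 20.0 ± 5.44 CPM. Of 32 claudins 6 were detected, Cldn12 (172 ± 4.71 CPM) and Cldn1 (171 ± 15.8 CPM) highest, and of 11 aquaporins only Aqp1.

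All 19 genes of sterol and fatty acid synthesis were detected, with a median of 303 CPM, led by Scd2, Fasn (1140 ± 81.2 CPM), Scd1 (787 ± 9.99 CPM) and the regulator Srebf2 (661 ± 33.5 CPM). Of 20 basement membrane genes 16 were detected, led by Col4a1 (506 ± 46.3 CPM) and the laminin chains Lama5 (473 ± 26.9 CPM) and Lamb1 (403 ± 50.5 CPM). Of 20 integrins 14 were detected, led by Itgb1 (1152 ± 42.9 CPM) and Itga3 (591 ± 25.1 CPM). Of 49 keratins 7 were detected, all others being at or below 0.769 CPM.

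The following tests were chosen after the result was seen, except those of depth and of shared reads for the tubule markers and of scaling for ribosomal RNA. No biological explanation was tested for any pattern, since there was 1 group.

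7 of 12 distal convoluted tubule markers, Slc12a3 among them, had 0 counts while their regulators were expressed. A detected protein-coding gene at the median level would have 54.0 counts over the 3 libraries. Depth is thus argued against only for markers at that level. The median was taken over detected genes alone, so depth stays open for markers expressed at lower levels. Reads shared with annotated transcripts are argued against, since at most 0.22% of the 50-base stretches of any of the 7 occur in another gene. Copies outside annotated transcripts were not searched, so reads lost to them stay open. An endothelial or blood cell line as the source is argued against by Pax2, Pax8 and Cdh16, all at 82.4 CPM or more, although these genes are also expressed in epithelia outside the kidney tubule. A mesenchymal source was part of the same test but stays open. Of the mesenchymal genes 7 of 9 were detected, beside 18 of 23 epithelial genes. Expression under the limit of 2.20 CPM cannot be told apart from absence, since 0 counts fit both.

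6 neighbouring mitochondrial messages had 0 counts. A hypothesis is that reads matching nuclear copies were dropped: the lowest shared portion among the uncounted messages other than mt-Atp8 was 98.0%, against 62.2% at most among the counted ones, and the nuclear pseudogenes that match these messages on chromosome 1, 24612407 to 24615565, had 0 to 1 counts each. Short length is argued against, since the longest uncounted message would have 232 counts at the lowest count per base of the counted ones. For mt-Atp8 the shared portion was 0%, with 60.3 counts predicted in the same way, and shared reads cannot be told apart from another cause, since the search covered annotated transcripts and not the genome between them.

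Nuclear ribosomal RNA differed 1.64-fold between replicates 1 and 3. The median log2 ratio of 982 genes with at least 100 counts between these replicates was 0.0223 (SD 0.17), against 0.71 for ribosomal RNA. The trimmed mean scaling sets the ratio of most genes near 0, so this median could not test scaling of the libraries. A change of scale shifts all genes alike, so the gap between ribosomal RNA and these genes does not depend on it. Mitochondrial ribosomal RNA was 1.5-fold higher in replicate 1 than in replicate 3, but at 791, 464 and 529 CPM in replicates 1, 2 and 3 its order differed. Uneven removal of ribosomal RNA cannot be told apart from other differences between the libraries, since both mitochondrial ribosomal RNAs were already among the genes found to vary and so give no separate test. Why Lars2 varied with them was not tested.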
